A study of Drosophila melanogaster with 63 samples.

How the data were processed

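The series holds 63 samples of Kc167, a female cell line from Drosophila embryos, and of a derived line that per the labels expresses Mod(mdg4) fused to GFP. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with antibodies against NURF301, CP190, Su(Hw), Mod(mdg4)67.2 or GFP. A peak list was used for 46 samples in 16 groups. The other 17 samples are input chromatin and enter no comparison, because no list belongs to them here. Knockdown cells received 5 ug of double-stranded RNA against Nurf301, Cp190 or su(Hw) and were kept for 4 days, per the labels. The mock samples fall into 2 series that the labels tell apart only by their titles. The mock series is numbered in the style of the NURF301 and CP190 knockdowns, and the mock2 series in the style of the Su(Hw) knockdown.

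Peaks were called by the authors in each library separately. The submitters' processing notes name Bowtie2 2.4.2, SAMtools 1.12, Picard 2.25.2 and MACS2 2.2.7.1, without their settings, the control library or the genome build. Each deposited list gives a score, which the values show to be 10 times the -log10 q with its decimals removed. It also gives a ratio, the fold enrichment of the summit over the expected local background as the authors deposited it. The -log10 p and the -log10 q at the summit are further deposited columns. Score, ratio, p and q are the authors' values. They were used here only to rank peaks within a list, for the depth check and, for q, to set thresholds in alternative settings. Sequence names and chromosome extents are those of Release 6 of the genome, although the build is not given in the labels. Genes came from the RefSeq annotation of that release and gave names and neighbours only. Coordinates printed are those of the peaks, counted from 1. Peaks outside the 6 main chromosomes (2L, 2R, 3L, 3R, 4 and X) were left out of the comparisons.

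The lists were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The number of reads per library is not given in the sources used here, so the number of peaks stands as the measure of depth. Peaks of the libraries of an antibody were merged where they shared at least 1 bp. A reference site had a peak in at least 4 of the 6 mock libraries, or in at least 2 of 3 for Mod(mdg4)67.2 and GFP. For a mock library, recovery was measured at sites with a peak in at least 3 of the 5 other mock libraries, so that no library chose its own reference. The recovery of the thinned mock lists described below is an exception. It was measured at the reference sites of all 6 mock libraries, which each library helped to choose. The annotation holds no strand. A site within 500 bp of either annotated end of a protein-coding gene was therefore called a gene boundary site, in place of a transcription start.

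Each knockdown was compared with all 6 mock libraries of the same antibody, in 8 comparisons. This pools 2 mock series that differ. CP190 lists held 10095 to 10553 peaks in the mock series and 5984 to 8813 in mock2. Su(Hw) lists held 3990 to 4607 and 5165 to 5358. The SD over 6 mock libraries and the pooled tests therefore include a difference between series. Peak numbers (on the log2 scale) and recovery were compared by exact two-sided permutation tests over all 84 splits of the libraries, whose two-sided p is 2 times the share of splits in the smaller tail and is at least 0.0238. The CP190 knockdown has 2 libraries per antibody and 28 splits, so this two-sided p is at least 0.0714. A log2 ratio of peak numbers is the difference between the mean log2 numbers of both groups. Values against the mock series with the matching titles are given beside them, where 3 against 3 libraries cannot go below 0.1. Each merged site was tested by a two-sided Fisher exact test of presence, with Benjamini-Hochberg adjustment over the sites that could reach 0.05 by their number of peaks. A site called lost or gained had an adjusted p under 0.05. The dependence on a partner protein was measured as a Mantel-Haenszel odds ratio of having no peak, at sites with against sites without the partner, within 10 strata of site strength. Where its log2 was not finite, 1 artificial site of each kind was added in a stratum of its own. The log2 odds ratio was compared between libraries by the exact permutation test and adjusted over 5 comparisons. Recovery within 40 classes of co-bound proteins was tested the same way and adjusted over the classes; classes under 50 sites were not tested. Overlaps were compared with 1000 random placements on the same chromosome (one-sided) and as odds ratios over 1 kb bins within boundary and other bins. Of 17 gene lists, each was tested for members with a boundary site by a two-sided Fisher exact test against all other protein-coding genes (13922 in all), adjusted over 68 tests. Members whose boundary sites had no peak in any knockdown library were tested likewise over 136 tests. The lists were insulator protein genes, chromatin remodeller genes, Hox genes, heat shock genes, ecdysone response genes, JAK/STAT pathway genes, innate immunity genes, Polycomb and Trithorax group genes, cell cycle genes, ribosomal protein genes, histone genes, loci linked with insulators, and markers of hemocytes, neurons, muscle, fat body and germline. The symbol calypso was not found in the annotation. P-values of the tests between libraries measure only the spread between these samples, since nothing in the labels says that replicates were separate cultures. The p-values of the overlaps and of the gene lists count sites or genes and hold no spread between samples.

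Named sites followed a fixed rule. For each knockdown these were the 10 strongest gene boundary sites and the 5 strongest other sites with a peak in every mock and no knockdown library. To these came the 5 strongest boundary sites with a peak in every library, up to 5 sites with a peak only in the knockdown, and members of the gene lists. Strength was the mean percentile of the authors' fold within each mock list. For the map, the 5 strongest reference sites of each antibody and of the sites shared by all 4 proteins were named. Comparisons, tests, this rule, the gene lists and most alternative settings were fixed before the data were examined. The gene boundary in place of the transcription start, thinned lists, a threshold of 20 on the -log10 q, the omission of both NURF301 mock libraries with few peaks, matched draws of genes, recovery among lists with fractional pileups and the histone list without HisCl1, HisRS and HisT were chosen after the data were seen.

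To check depth, the read pileup and the background at each summit were solved from the deposited fold and -log10 p. Mock peaks were then thinned by binomial draws to the background of the knockdown lists and kept where they still reached the smallest -log10 p of those lists. On simulated peaks, all of 2599 pileups and backgrounds were recovered (100.0%). The solved pileups were whole numbers (within 0.05) for at least 99.8% of peaks in 23 lists and for at most 20.8% in the other 23. A scaling of the ChIP library to its control by the caller would give such fractions. Fractional pileups occurred in 18 of 22 knockdown lists and in 4 of 21 mock lists, so this feature of the authors' processing goes partly with the groups.

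The per-site test was also checked on simulated data made from the mock lists. Presence was drawn independently for each site and library, so all simulated libraries had the same depth. False calls that unequal depth would give were therefore not simulated. With 0 sites changed the test called none. With 200 sites set to absent it called 0, and with 2000 it called all of them, with 2 to 12 false calls, when 3 knockdown libraries were compared with 6. With 2 knockdown libraries it called 0 even at 2000. It can therefore find only changes that cover a large part of the sites tested. A simulated log2 odds ratio of 3 was estimated as 3.04 for CP190 and 2.97 for NURF301. Alternatives were a stricter q threshold, summits extended by 150 bp in place of whole peaks, sites in every mock library, each mock series alone, pairing by replicate number, other strength strata, other overlap rules, a 1000 bp boundary window and each library left out in turn; the p of permutation tests under these alternatives are unadjusted unless stated. Motifs were not run, since no genome sequence was used here.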

Results

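The data map NURF301, the largest subunit of the nucleosome remodelling factor NURF, and proteins of the gypsy chromatin insulator in Kc167 cells. Su(Hw) is the zinc finger protein that binds DNA at gypsy insulators. CP190 and Mod(mdg4)67.2 are BTB domain proteins of the same complex. ChIP-seq lists were available for mock cells with each antibody and for knockdowns of NURF301, CP190 and Su(Hw). The 6 mock libraries of NURF301 held 4608 to 8226 peaks each, those of CP190 5984 to 10553 and those of Su(Hw) 3990 to 5358. The 3 Mod(mdg4)67.2 libraries held 1685, 2048 and 2813 peaks. In cells with Mod(mdg4) fused to GFP, the 3 GFP libraries held 949, 2204 and 2849. Within an antibody, the smaller of 2 mock lists shared 95.1% to 99.9% of its peaks with the larger for NURF301, CP190, Su(Hw) and Mod(mdg4)67.2, and 93.1% to 99.9% for GFP.

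**Figure D1:**
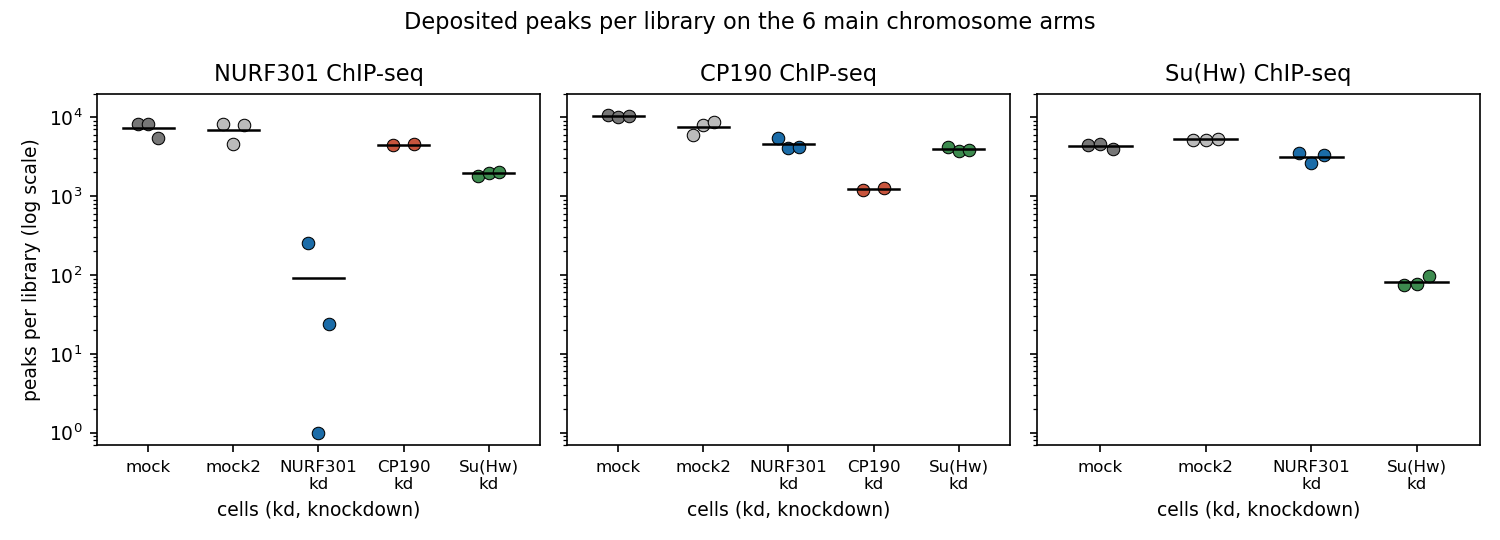
Number of peaks per library on a log scale, by antibody and by cells; each point is a library and each bar is the mean of its group. NURF301 lists held 4608 to 8226 peaks in mock cells and 1, 24 and 253 after NURF301 knockdown.

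The first question was where NURF301 lies relative to the insulator proteins in mock cells. NURF301 had 7360 reference sites, CP190 8308, Su(Hw) 4525 and Mod(mdg4)67.2 2039. Gene boundaries held 67.5% of the NURF301 sites and 53.8% of the CP190 sites, against 15.2% and 15.0% of randomly placed sites. For Su(Hw) this share was 15.9%, close to the 15.0% of random placement, and for Mod(mdg4)67.2 it was 24.4%. The strongest NURF301 sites lay at CG41128 (3R, 3748468 to 3751558), PlexB, which encodes a semaphorin receptor (4, 42225 to 44160), Maf1, a repressor of RNA polymerase III (2R, 1526113 to 1527716), Nipped-A and CG17528. Those of CP190 lay inside Rbfox1, which encodes an RNA-binding protein (3L, 10507832 to 10508484), at PGRP-LA, at CG31776 and Pgant4, near side-IV and inside Myo81F. Su(Hw) was strongest near oaf (2L, 2504982 to 2506146), near CG2861, at tw and fz3, inside eys and CG9967 and inside the glutamate receptor gene mGluR. Mod(mdg4)67.2 was strongest at spineless (ss; 3R, 16373968 to 16374799), inside twi, at Obp56c, inside Mp and inside the neuronal fate gene pros.

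NURF301 overlapped CP190 at 5496 of its 7360 sites (74.7%; random placement 9.85%), Su(Hw) at 1127 (15.3%; random 5.59%) and Mod(mdg4)67.2 at 1010 (13.7%; random 2.15%). Each one-sided p was 0.001, the smallest that 1000 placements can give. With only sites present in every mock library the overlaps were 74.4%, 8.26% and 7.03%. Within boundary and other bins, the odds ratios were 26.4 for CP190 (95% interval 24.8 to 28.1), 3.39 for Su(Hw) (3.14 to 3.65) and 7.41 for Mod(mdg4)67.2 (6.77 to 8.11). Across the 6 NURF301 libraries the overlap with CP190 was 76.2% ± 7.40 (SD, n = 6). CP190 without the other insulator proteins lay at 4364 NURF301 sites (59.3%), and 84.3% of these were gene boundaries. All 3 insulator proteins lay at 985 NURF301 sites, of which 36.1% were boundaries. The strongest of the sites with all 4 proteins lay near CG3355 (2L, 4660795 to 4661446), inside Mp (3L, 7012214 to 7012714), inside CG15890 and near CG5386 and CG5790. No insulator protein mapped here lay at 1844 NURF301 sites (25.1%).

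Nearly every Mod(mdg4)67.2 site carried CP190 (99.5%) and Su(Hw) (98.1%), and 49.3% carried NURF301. The GFP-tagged protein tested the antibody map: 86.3% of the Mod(mdg4)67.2 sites overlapped a GFP site, against 2.05% of randomly placed sites. Single GFP libraries held 86.5%, 97.3% and 45.6% of the Mod(mdg4)67.2 sites (76.4% ± 27.3, SD, n = 3). The lowest value came from the GFP library with 949 peaks. Conversely, 85.5% ± 10.4 (SD, n = 3) of the 2016 GFP reference sites had a peak in a Mod(mdg4)67.2 library. The smallest -log10 q in the GFP lists was 1.34, against at least 6 in the other lists, so the GFP lists reach weaker peaks.

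At Su(Hw) sites NURF301 went with Mod(mdg4)67.2. NURF301 lay at 965 of 1938 Su(Hw) sites with Mod(mdg4)67.2 (49.8%) and at 131 of 2587 without it (5.06%), a log2 odds ratio of 4.22. Sites such as those at tw and fz3 (X, 784007 to 785058), sgg (X, 2679031 to 2680010) and mGluR (4, 941241 to 941928) carried all 4 proteins. Within deciles of Su(Hw) strength the log2 odds ratio was 5.07 (95% interval 4.70 to 5.44), and at Su(Hw) sites with CP190 it was 4.34 (3.98 to 4.70). In the weakest decile 79.6% of the sites with Mod(mdg4)67.2 carried NURF301, and in the strongest 40.2%. Sites are not independent replicates, so these intervals cover counting error only.

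**Figure D2:**
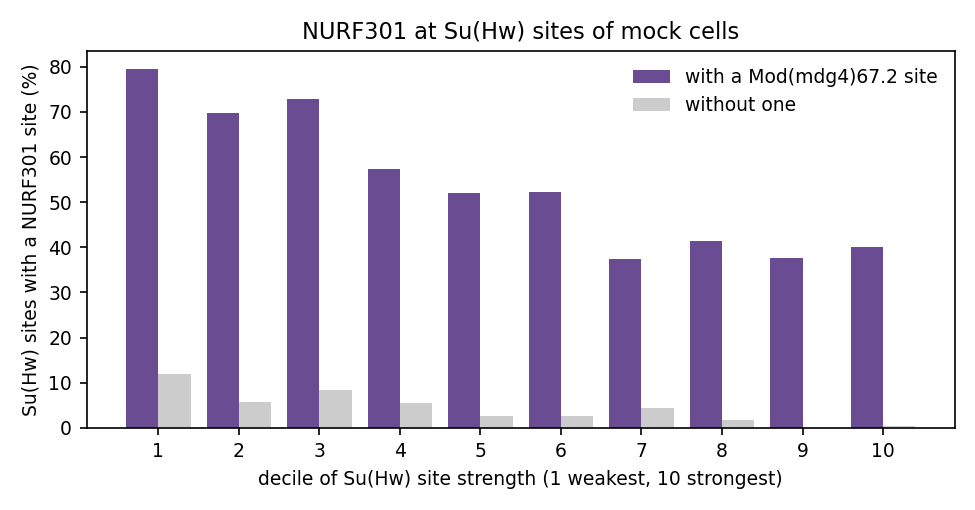
Percent of Su(Hw) reference sites of mock cells that carry a NURF301 site, by decile of Su(Hw) strength, for sites with and without Mod(mdg4)67.2. Sites with Mod(mdg4)67.2 are the higher bar in all 10 deciles.

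NURF301 lay at the boundaries of cell cycle and ribosomal protein genes more often than at those of other genes. All 28 cell cycle genes had a NURF301 boundary site, against 50.4% of other genes (Fisher exact two-sided, adjusted p = 1.03e-07). By the same Fisher exact test, ribosomal protein genes had 75 of 85 (adjusted p = 4.57e-12), Polycomb and Trithorax group genes 22 of 25 (0.00153), germline markers 13 of 14 (0.0156) and chromatin remodeller genes 18 of 22 (0.0297). Shares were lower for muscle markers, 2 of 15 (0.0288), and for the histone list, 7 of 118 (3.98e-24), whose symbol pattern also took in HisCl1, HisRS and HisT, which are not histone genes. Without these 3 it was 4 of 115 (3.27e-27): His2Av, His3.3A, His3.3B and His4r had a site and none of the 111 genes of the repeated cluster, where reads cannot be placed uniquely. Lists that did not pass were insulator protein genes (14 of 21), Hox genes (5 of 8), heat shock genes (10 of 19), ecdysone response genes (6 of 22), JAK/STAT genes (8 of 13), innate immunity genes (9 of 24), insulator-linked loci (10 of 18), hemocyte markers (6 of 25), neuronal markers (7 of 23) and fat body markers (2 of 11). CP190 boundary sites passed for cell cycle genes, 24 of 28 (adjusted p = 0.000333), and ribosomal protein genes, 67 of 85 (3.59e-08, Fisher exact), against 46.7% and 46.6% of other genes. The histone list was again low, 7 of 118 (3.81e-21), and 4 of 115 without those 3 genes (3.55e-24). No list passed for Su(Hw) or Mod(mdg4)67.2. With the corrected histone list, its share passed for Su(Hw), 0 of 115 (0.00718), as did the lower share of hemocyte markers for NURF301 (0.049, Fisher exact).

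The knockdown of NURF301 asked how far the peaks of NURF301 itself, of CP190 and of Su(Hw) depend on NURF301. NURF301 peaks were almost absent after its own knockdown. The strongest boundary sites that fell to no peak in any knockdown library lay at CG40191 (2R, 1263371 to 1265245), the MAP kinase gene rl (2R, 1070701 to 1072760), anne, the adaptor gene Crk, 4E-T, CG10395, OXA1L, gus, Vps11, and Dyrk3 with Cadps. Away from boundaries they lay inside myo, a TGF-beta ligand gene, inside ovo, inside CaMKII, and near Spf45 and CG42402. Peaks per library fell from 7098 ± 1627 (SD, n = 6) to 92.7 ± 139 (SD, n = 3), a difference of -8.57 between mean log2 numbers (exact permutation p = 0.0238), while the log2 ratio of the 2 means was -6.26. Against the matching mock series alone the log2 ratio was -8.61 (exact permutation p = 0.1). Recovery of reference sites fell from 85.9% ± 19.7 (n = 6) to 1.25% ± 1.89 (n = 3; exact permutation p = 0.0238). Of 7556 sites tested 3898 were lost by the Fisher exact test (highest adjusted p = 0.0231) and 0 gained, with 0 gained at an unadjusted p under 0.05. No boundary site had a peak in every knockdown library. The knockdown lists held 253, 1 and 24 peaks, and the log2 ratio was -6.47 without replicate 2, the library with 1 peak. Without both NURF301 mock libraries with few peaks, mock replicate 3 and mock2 replicate 2, 7094 sites were lost. In thinned mock lists 0 were, and recovery differed by -24.2 percentage points in place of -84.6, but the depth of these lists rests on the few sites shared with the short knockdown lists, so they say little here.

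CP190 kept peaks at many gene boundaries that also carried NURF301 and had few left at sites with Su(Hw) alone. Its strongest sites with a peak in all 6 mock and all 3 NURF301 knockdown libraries lay at CG31776 and Pgant4 (2L, 3471931 to 3472824), Oatp30B and CG17855, CG3407, CG43332 and CG46301, and CG9886. Among the sites with a peak in every mock and in no knockdown library were the strongest CP190 site, inside Rbfox1 (3L, 10507832 to 10508484), and those inside Myo81F and near the receptor gene Toll-4, CG3650 and eIF4B. At boundaries they lay at CG12477 (3L, 18723084 to 18723936), CG42810, CG10943 and CG32107, the glutamate transporter gene Eaat1, dpr20, CG33299, DIP1, SP1173, the histone methyltransferase gene gpp, and CG4702. Peaks per library fell from 8983 ± 1784 (SD, n = 6) to 4593 ± 756 (SD, n = 3), a log2 ratio of -0.95 (exact permutation p = 0.0238). The log2 ratio was -1.19 against the matching mock series (exact permutation p = 0.1) and -1.51 among peaks with a -log10 q of at least 20 (exact permutation p = 0.0238). The median -log10 q was 21.7 to 34.5 in the knockdown lists and 58.9 to 153 in the mock lists. That threshold therefore took a larger share of the knockdown peaks. Recovery fell from 86.9% ± 16 (n = 6) to 52.7% ± 8.26 (n = 3; exact permutation p = 0.0476). The difference of -34.2 percentage points was -54.8 against the matching mock series (exact permutation p = 0.1).

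By class, CP190 recovery at sites with Su(Hw) alone fell from 80.0% ± 29.3 (n = 6) to 6.07% ± 5.59 (n = 3), and at sites with Su(Hw) and Mod(mdg4)67.2 from 99.3% ± 1.53 to 35.9% ± 17.9. Sites with none of these proteins fell from 64.5% ± 35.0 to 6.65% ± 0.856. Sites with all of them fell from 99.97% ± 0.0842 to 84.8% ± 11.1 (exact permutation p = 0.0238 and adjusted p = 0.0366 for each of these classes). At sites with NURF301 alone recovery was 87.6% ± 15.1 in mock and 69.9% ± 8.33 in knockdown libraries, which did not pass (exact permutation p = 0.143). The lowest mock library stood at 23.7% at sites with Su(Hw) alone and at 13.6% at sites with none of these proteins. These classes had the lowest median site strength (percentiles of 37.6 and 34.5), against 54.4 with NURF301 alone. Strength did not set the whole order, since sites with Su(Hw) and Mod(mdg4)67.2 had a median of 65.4. The log2 odds ratio of a missing CP190 peak at NURF301 sites against other sites was -4.26 ± 0.46 (n = 3) after knockdown. In mock libraries it was -3.44 ± 3.54 (n = 6), from -7.82 to -5.14 in the mock series and from -2.14 to 1.08 in mock2. In mock replicates 2 and 3, 0 of 5413 NURF301 sites lacked a peak. Their values, -7.82 and -6.34, were finite only because 1 artificial site of each kind was added. The size of the mock mean, its SD and the difference from the knockdown libraries therefore depend on that addition. The difference between knockdown and mock libraries was -0.82 (exact permutation p = 0.738). That difference was -2.67 with summits extended by 150 bp (exact permutation p = 0.0238), -2.27 against the matching mock series (exact permutation p = 0.1), -1.97 in thinned lists, -0.01 without strength strata and between -1.53 and -0.39 with each library left out. Of ribosomal protein genes with a CP190 boundary site, 1 of 67 (RpS5b) had no peak in any knockdown library, against 16.2% of other genes with such a site (Fisher exact two-sided, adjusted p = 0.00854). Among genes drawn with matching site strength 5.32 of 67 did on average (permutation p = 0.0237 over 10000 draws, one-sided, chosen after the result was seen). No cell cycle gene of 24 did, a difference that did not pass (Fisher exact, adjusted p = 0.219). No CP190 site passed the per-site Fisher test (0 of 4759 tested; 2301 at an unadjusted p under 0.05). The 1059 sites in every mock and no knockdown library had an adjusted p of 0.0535. Leaving out mock2 replicate 1 gave 2299 lost sites, and leaving out mock2 replicate 2 or mock replicate 1, 2 or 3 gave 1059, 1059, 1061 and 1063. Lost sites numbered 1304 among peaks with a -log10 q of at least 20 and 923 in thinned lists. All 3 knockdown lists had fractional pileups, and the only mock list of this kind, mock replicate 3, held 10467 peaks.

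**Figure D3:**
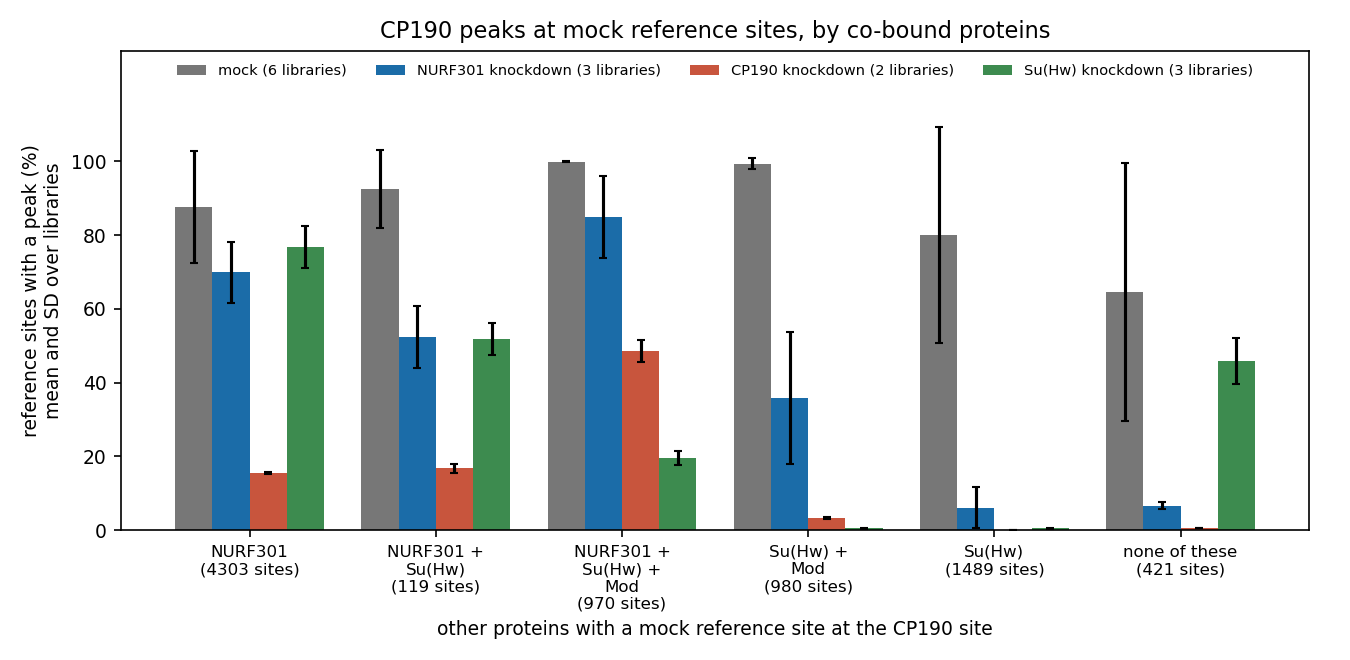
Percent of CP190 reference sites with a CP190 peak (mean and SD over libraries), by the other proteins at the site, in mock cells and in each knockdown. After NURF301 knockdown the sites with Su(Hw) alone stood at 6.07%, and after Su(Hw) knockdown the sites with NURF301 alone stood at 76.9%. At sites with Su(Hw) alone the lowest mock library stood at 23.7%.

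Su(Hw) lost part of its sites after NURF301 knockdown. Boundary sites that fell to no peak in any knockdown library lay at Jon65Aii and Jon65Aiii (3L, 6051691 to 6052408), CG13127, CG43373, Cln3, CG42826, the Hedgehog pathway gene ci (4, 47165 to 47844), CG14246, Daao2 and CG17375, CG33281, and Mnn1, which encodes menin. Others lay near MFS17, Mur11Da, CG2955 and CG3528 and inside sbm. Su(Hw) kept a peak in every library at CG14736, CG43056, the kinase gene sgg, CG17237, and Recs1 with CG42500. Peaks per library fell from 4801 ± 524 (SD, n = 6) to 3160 ± 476 (SD, n = 3), a log2 ratio of -0.61 (exact permutation p = 0.0238). It was -0.48 against the matching mock series (exact permutation p = 0.1). Recovery fell from 92.2% ± 9.01 (n = 6) to 67.8% ± 10.3 (n = 3; exact permutation p = 0.0238). Of 1533 sites tested 411 were lost by the Fisher exact test (highest adjusted p = 0.0444) and 0 gained, with 1 gained at an unadjusted p under 0.05. Recovery fell in the class with CP190, Mod(mdg4)67.2 and NURF301 from 99.5% ± 0.658 (n = 6) to 89.0% ± 9.73 (n = 3). In the class with CP190 alone it fell from 95.2% ± 6.55 to 67.0% ± 11.3 (exact permutation p = 0.0238, adjusted p = 0.0366 for both). The class without other proteins went from 79.2% ± 23.5 to 38.9% ± 12, with an adjusted p of 0.0705 (exact permutation p = 0.0476). The log2 odds ratio of a missing peak at NURF301 sites differed by -0.79 between knockdown and mock libraries (exact permutation p = 0.643), by -0.38 in thinned lists and by -1.34 to -0.15 with each library left out.

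The Su(Hw) comparison after NURF301 knockdown depended on the settings. In thinned mock lists recovery was 86.8% ± 9.66 (n = 6), and the difference of -19.0 percentage points did not pass (exact permutation p = 0.0714). These lists were scored at sites that each mock library helped to choose. Mock replicate 3, which thinning left at 3990 peaks, stood at 85.3% there and at 77.4% at sites chosen by the other mock libraries. The change in recovery therefore mixes depth with the choice of sites. Against thinned lists 246 sites were lost. Among peaks with a -log10 q of at least 20 the log2 ratio of peak numbers was -1.07 and recovery differed by -38.6 percentage points, in place of -0.61 and -24.4 (exact permutation p = 0.0238 for both). Leaving out knockdown replicate 2 or 3 gave 0 lost sites, leaving out mock replicate 3 gave 763, and gained sites were 1 without mock replicate 2 and 6 with summits extended by 150 bp. Among lists with fractional pileups, the 3 mock lists held 5235 ± 107 peaks (SD, n = 3) and the 3 knockdown lists 3160 ± 476 (SD, n = 3).

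After CP190 knockdown, the comparison with mock cells first shows how far CP190 itself was removed. CP190 sites without a peak in either knockdown library included the strongest, inside Rbfox1 (3L, 10507832 to 10508484), and those near side-IV and Toll-4 and inside Myo81F and pan, the TCF gene (4, 89539 to 90446). At boundaries they lay at Oatp30B and CG17855 (2L, 9539851 to 9540664), CG43181, CG43332 and CG46301, CG42269 and CG6602, CG9886, CG12477, CG45072 with the HIF alpha gene sima, CG17636, CG11327 and Nhe3, and uri with CG11414. Sites with a peak in every library lay at CG31776 and Pgant4 (2L, 3471931 to 3472824), Cyp6a16, the nuclear receptor gene Hnf4 with raw, stol, and Remo with CG15743. Peaks per library numbered 8983 ± 1784 (SD, n = 6) in mock and 1242 ± 54.4 (SD, n = 2) in knockdown cells, a log2 ratio of -2.83 with the smallest p possible (exact permutation p = 0.0714). Against the matching mock series it was -3.06 (exact permutation p = 0.2). Recovery was 86.9% ± 16 in mock and 14.5% ± 0.562 in knockdown libraries (exact permutation p = 0.0714). The per-site Fisher test called 4452 of 4941 sites lost (highest adjusted p = 0.0396) and 0 gained, with 0 gained at an unadjusted p under 0.05. It called 0 lost when any of the 6 mock libraries was left out, since 5 against 2 libraries make the smallest attainable p larger, and 17 gained with summits extended by 150 bp. Recovery at sites with NURF301, Su(Hw) and Mod(mdg4)67.2 was 48.6% ± 2.99 (n = 2), at sites with NURF301 alone 15.4% ± 0.279 and at sites with Su(Hw) alone 0.101% ± 0.0475. Among lists with fractional pileups, mock replicate 3 held 10467 peaks and the knockdown lists 1203 and 1280.

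NURF301 peaks after CP190 knockdown addressed whether NURF301 needs CP190 at its sites. The strongest NURF301 sites, at CG41128, PlexB, Maf1, Nipped-A and CG17528, had a peak in all mock and both knockdown libraries. Sites with a peak in every mock and no knockdown library lay at CheB93a (3R, 21408253 to 21408879), CG4702, the Mediator gene MED26, stol, CG31140, Gycbeta100B, Actn3 and AhcyL2, CG43332 and CG46301, Ufd4 with the heart gene Hand, and CG33462. Away from boundaries they lay inside the mesoderm gene twi (2R, 23001769 to 23002364), inside Rbfox1 and near CG5214, CG3650 and Oseg2. All 5 Hox genes with a NURF301 boundary site (Dfd, Scr, Ubx, abd-A and lab) had no peak there in either knockdown library, against 18.0% of other genes with such a site (Fisher exact two-sided, adjusted p = 0.00854). Among genes drawn with matching site strength 2.07 of 5 did on average (permutation p = 0.0027 over 10000 draws, one-sided, chosen after the result was seen). Both tests treat genes as independent and cover boundary sites only. Over all NURF301 sites within the gene or 500 bp around it, a peak remained in any knockdown library at 2 of 2 for Antp and 2 of 4 for Abd-B. For Scr it remained at 1 of 3, for Ubx at 1 of 2 and for abd-A at 0 of 1. Of the Hox genes 1 of 8, Ubx, had a CP190 boundary site in mock cells. Of the chromatin remodeller genes with a NURF301 boundary site, 0 of 18 had no peak in either knockdown library, which did not pass (Fisher exact, adjusted p = 0.397).

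Peaks of NURF301 per library numbered 7098 ± 1627 (SD, n = 6) in mock and 4489 ± 121 (SD, n = 2) in CP190 knockdown cells, a log2 ratio of -0.62 (exact permutation p = 0.0714, the smallest possible). Against the matching mock series it was -0.67 (exact permutation p = 0.2), and among peaks with a -log10 q of at least 20 it was -1.07 (exact permutation p = 0.0714). The median -log10 q was 22.4 and 23.7 in the knockdown lists and 26.1 to 89.6 in the mock lists. That threshold therefore took a larger share of the knockdown peaks. Recovery was 85.9% ± 19.7 and 57.2% ± 1.51 (exact permutation p = 0.214). The difference of -28.7 percentage points was -10.1 at sites present in every mock library (exact permutation p = 0.214). At sites with CP190 alone recovery was 93.9% ± 9.52 (n = 6) in mock and 75.4% ± 1.90 (n = 2) in knockdown libraries. At sites with CP190, Su(Hw) and Mod(mdg4)67.2 it was 76.6% ± 31.1 and 28.1% ± 2.66. At sites without insulator proteins it was 74.4% ± 35.1 and 30.4% ± 0.0767. The lowest mock libraries stood at 77.6%, 31.2% and 23.8% in these classes, close to the knockdown values. The order of the classes after knockdown was also that of their median site strength (percentiles of 62.1, 25.5 and 31.9). The log2 odds ratio of a missing NURF301 peak at CP190 sites was -1.50 ± 0.16 (n = 2) after knockdown and -1.12 ± 1.5 (n = 6) in mock libraries (difference -0.38, exact permutation p = 1). The sign of that difference depended on the libraries and the setting: it was 0.39, 0.82, 0.75 and 1.3 without mock replicate 1, mock replicate 2, mock2 replicate 1 or mock2 replicate 3, 0.18 without strength strata, 0.35 in thinned lists and -1.08 against the matching mock series. The Fisher test called 0 of 1091 sites lost, with 352 at an unadjusted p under 0.05, in a design that could not call even 2000 simulated losses.

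**Figure D4:**
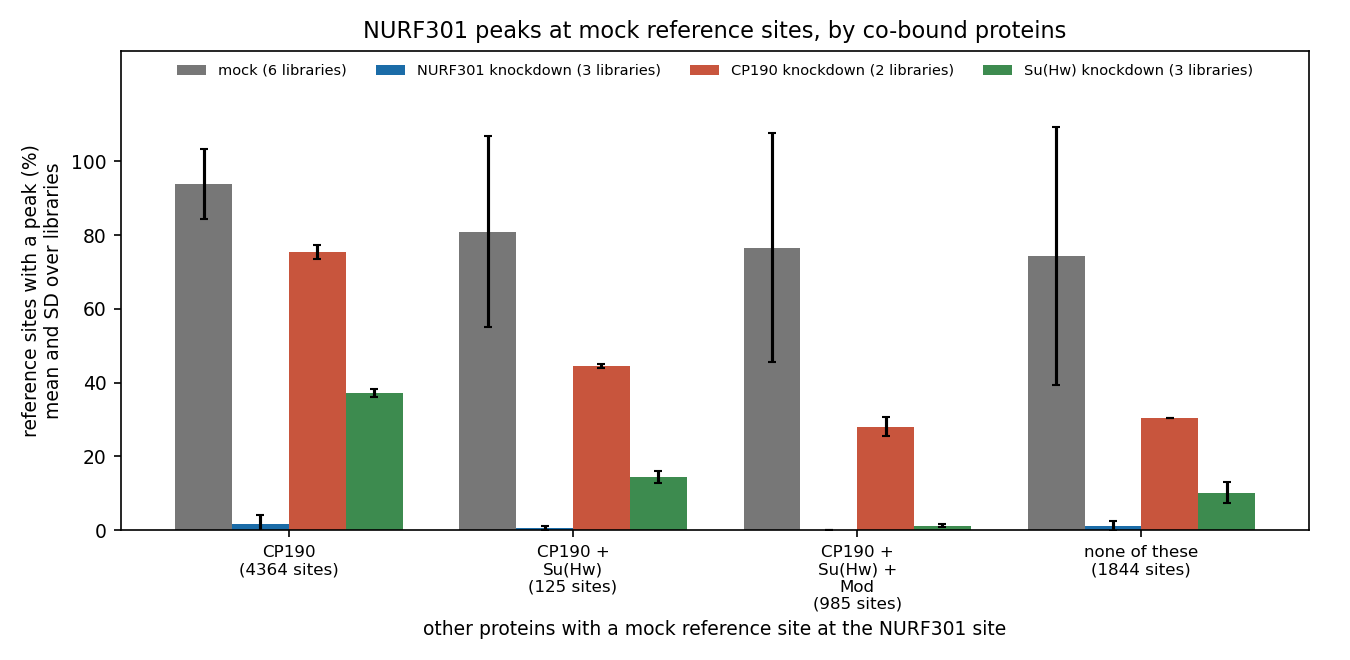
Percent of NURF301 reference sites with a NURF301 peak (mean and SD over libraries), by the insulator proteins at the site, in mock cells and in each knockdown. After Su(Hw) knockdown the sites with CP190 alone stood at 37.2% and those with all 3 insulator proteins at 1.25%. The former class also had the higher median site strength in mock cells.

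After Su(Hw) knockdown, Su(Hw) peaks were nearly absent. Sites that fell to no peak lay near oaf (2L, 2504982 to 2506146) and CG2861, inside eys and CG9967, inside mGluR and inside the teneurin gene Ten-a. At boundaries they lay at tw and the Wnt receptor gene fz3 (X, 784007 to 785058), CG14736, CG43056, sgg, CG17237, Recs1 and CG42500, CG15254 and Semp1, CG7239, CG7408, and the FGF receptor gene htl. Peaks remained in every library at 49 sites that had one in every mock library. The strongest of these at boundaries lay at SP1173 (3L, 6703236 to 6704030), the mechanosensory channel gene nompC, Atet, CG30095 and CG43658, each with NURF301, CP190 and Mod(mdg4)67.2 in mock cells. Peaks per library fell from 4801 ± 524 (SD, n = 6) to 82.3 ± 11.9 (SD, n = 3), a log2 ratio of -5.87 (exact permutation p = 0.0238). Against the mock2 series it was -6.00 (exact permutation p = 0.1). Recovery fell from 92.2% ± 9.01 (n = 6) to 1.82% ± 0.264 (n = 3; exact permutation p = 0.0238). Of 4881 sites tested 3726 were lost by the Fisher exact test (highest adjusted p = 0.0156) and 0 gained, with 0 gained at an unadjusted p under 0.05.

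The Su(Hw) knockdown then showed NURF301 peaks missing well beyond Su(Hw) sites. Sites that fell to no peak lay at CG4702 (3R, 12121037 to 12121706), MED26, stol, CG13766, the transcription factor gene Mitf, Ak6 and stil, the translation factor gene eIF4G1, PGRP-LA, CG41378 and CG7565. Others lay near CG42598, the homeobox gene Rx and CG12547 and inside CG31886 and twi. CG41128, PlexB, Maf1, Nipped-A and CG17528 kept a peak in all libraries. Peaks per library fell from 7098 ± 1627 (SD, n = 6) to 1937 ± 107 (SD, n = 3), a log2 ratio of -1.84 (exact permutation p = 0.0238). Against the mock2 series it was -1.79 (exact permutation p = 0.1), and among peaks with a -log10 q of at least 20 it was -3.31 (exact permutation p = 0.0238). The median -log10 q was 14.6 to 18.1 in the knockdown lists and 26.1 to 89.6 in the mock lists. This threshold therefore took a larger share of the knockdown peaks, and the lower ratio is no separate evidence of loss. Recovery fell from 85.9% ± 19.7 (n = 6) to 25.1% ± 1.2 (n = 3; exact permutation p = 0.0238). Of 5107 sites tested 1456 were lost by the Fisher exact test (highest adjusted p = 0.0418) and 0 gained, with 0 gained at an unadjusted p under 0.05. The count was 2366 without mock2 replicate 2 and 4578 without both NURF301 mock libraries with few peaks, and 10 sites were gained with summits extended by 150 bp. All 5 Hox genes with a NURF301 boundary site lacked a peak there, which did not pass (Fisher exact, adjusted p = 0.204).

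Recovery of NURF301 fell to 1.25% ± 0.357 (n = 3) at sites with CP190, Su(Hw) and Mod(mdg4)67.2, from 76.6% ± 31.1 in mock libraries (n = 6). At sites with CP190 alone it fell from 93.9% ± 9.52 to 37.2% ± 1.13 and at sites without insulator proteins from 74.4% ± 35.1 to 10.1% ± 2.82 (exact permutation p = 0.0238, adjusted p = 0.0366 for these classes). In order, the lowest mock libraries stood at 31.2%, 77.6% and 23.8% in these classes, above the knockdown values. The order of the classes after knockdown was also that of their median site strength (percentiles of 25.5, 62.1 and 31.9). Peaks were missing at 97.2% ± 0.320 of the NURF301 sites with Su(Hw) and at 70.8% ± 1.39 of those without it (n = 3). The log2 odds ratio was 2.36 ± 0.22 (n = 3) after knockdown and -0.55 ± 1.74 (n = 6) in mock libraries. The difference of 2.91 did not pass (exact permutation p = 0.0714, adjusted p = 0.179). It was 4.03 without mock2 replicate 3, whose own value was 2.47 (exact permutation p = 0.0357), 3.86 with summits extended by 150 bp and 3.43 in thinned lists (exact permutation p = 0.0238 for both), and 2.96 with 5 strata (exact permutation p = 0.0476). These p are unadjusted; adjusted over 5 comparisons the value in thinned lists did not pass (adjusted exact permutation p = 0.0595). All 3 knockdown lists and none of the NURF301 mock lists had fractional pileups, so this feature cannot be separated from the knockdown.

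After Su(Hw) knockdown, CP190 peaks were missing at 92.6% ± 0.723 of the CP190 sites with Su(Hw) and at 25.8% ± 5.23 of those without it (n = 3). They were lost at tw and fz3 (X, 783951 to 785075), Recs1 and CG42500, CG7402 and Tsp74F, sgg (X, 2679079 to 2680042), ng4, CG15649, the chorion gene Cp7Fb, CG33158 and CG42514, CG43448, and to with CG11854, all of which carried Su(Hw) in mock cells. So did the sites near dpr21, CG10013, CG6414 and CG5386 and inside CG15890. Peaks stayed in every library at PGRP-LA (3L, 9333505 to 9334438), CG31776 and Pgant4, Oatp30B and CG17855, CG3407, and CG43181, which carried NURF301 and no Su(Hw). CP190 peaks were gained inside CG6154 (3R, 26266627 to 26267177), net (2L, 82686 to 83140) and CG9380 (2R, 25194295 to 25194756). Peaks per library fell from 8983 ± 1784 (SD, n = 6) to 3923 ± 276 (SD, n = 3), a log2 ratio of -1.17 (exact permutation p = 0.0238). Against the mock2 series it was -0.94 (exact permutation p = 0.1). Recovery fell from 86.9% ± 16 (n = 6) to 45.6% ± 3.30 (n = 3; exact permutation p = 0.0238). Of 5793 sites tested 2163 were lost and 3 gained by the Fisher exact test (highest adjusted p of the lost sites 0.0318). Lost sites numbered 3394 without mock2 replicate 1, and gained sites 5 without mock replicate 1, 5 in thinned lists and 14 with summits extended by 150 bp. Gene boundaries held 21.1% of the lost sites and 79.7% of the 3112 sites with a peak in every library.

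Recovery of CP190 fell to 0.515% ± 0.155 (n = 3) at sites with Su(Hw) alone and to 0.510% ± 0.177 at sites with Su(Hw) and Mod(mdg4)67.2, from 80.0% ± 29.3 and 99.3% ± 1.53 (n = 6). At sites that also carried NURF301 it fell from 99.97% ± 0.0842 to 19.7% ± 1.90 (exact permutation p = 0.0238, adjusted p = 0.0366 for these 3 classes). At sites with NURF301 alone it was 87.6% ± 15.1 in mock and 76.9% ± 5.67 in knockdown libraries (exact permutation p = 0.310), and at sites with none of these proteins 64.5% ± 35.0 and 45.8% ± 6.19 (exact permutation p = 0.357). The log2 odds ratio of a missing CP190 peak at Su(Hw) sites was 6.63 ± 0.26 (n = 3) after knockdown and -0.25 ± 1.56 (n = 6) in mock libraries. The difference of 6.89 had an exact permutation p of 0.0238 and, over the 5 comparisons of this kind, an adjusted p of 0.119, which did not pass. Of ribosomal protein genes with a CP190 boundary site, 1 of 67 (RpS5b) lacked a peak in all knockdown libraries, against 19.3% of other genes with such a site (Fisher exact two-sided, adjusted p = 0.00204). In draws matched for site strength 8.51 of 67 did on average (permutation p = 0.0013 over 10000 draws, one-sided, chosen after the result was seen). No cell cycle gene of 24 did (Fisher exact, adjusted p = 0.168). All 3 knockdown lists had fractional pileups, as did mock replicate 3 with its 10467 peaks.

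At loci linked with insulators, the cut locus (ct), where a gypsy insertion blocks enhancers in a classic mutant, had 6 Su(Hw), 7 CP190, 4 NURF301 and 3 Mod(mdg4)67.2 reference sites within the gene or 500 bp around it. After NURF301 knockdown 5 of the Su(Hw) sites and 4 of the CP190 sites had a peak in any library. After Su(Hw) knockdown 0 of the Su(Hw) sites and 1 of the CP190 sites had one. The yellow gene (y) had 1 reference site of each of the 4 proteins, and after Su(Hw) knockdown 0 of these sites of NURF301, CP190 and Su(Hw) had a peak. Antp had 6 CP190 sites, of which 4 had a peak after Su(Hw) knockdown, 3 after NURF301 knockdown and 1 after CP190 knockdown. Abd-B had 3 CP190 sites, all 3 with a peak after either Su(Hw) or NURF301 knockdown. These counts were not tested.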

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

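The tests on thinned lists, on lists with fractional pileups, between knockdowns and over other splits of the libraries were chosen only after the results they concern had been seen. So was the use against weak sites of the log2 odds ratios within strength strata, which were themselves stated before. Peaks outside the 6 main chromosomes, which enter no comparison, made up a larger share of the CP190 lists after CP190 knockdown than of any mock list: 0.399% on average (at least 0.331% in each of 2 libraries), against 0.176% on average and at most 0.236% in the 6 mock libraries. Their number was not larger, with 4 and 6 such peaks against 6 to 25 in the mock lists. Mean shares of 23.6% (NURF301 after NURF301 knockdown) and 0.344% (Su(Hw) after Su(Hw) knockdown) did not exceed the mock lists in every library, the lowest being 0 in both. No biological explanation of this share was tested. Of 12 groups of 6 mock values examined by Dixon's gap test for a single library far from the others, 0 held one. This test can miss 2 libraries that are low together. For NURF301 recovery, mock2 replicate 2 and mock replicate 3 stood at 55.9% and 65.7%, and the other mock libraries at 97.8% to 99.2%.

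The drop in recovered sites could reflect lower effective depth of the knockdown lists. Against mock lists thinned to the knockdown background, recovery still differed by -58.2 percentage points for NURF301 and -44.3 for CP190 after Su(Hw) knockdown (exact permutation p = 0.0238 for both). Thinned lists were scored at sites that each mock library helped to choose, which raises recovery. The shortest mock lists, hardly changed by thinning, recovered 55.9% (NURF301) and 59.3% (CP190) of sites chosen by the other mock libraries. Knockdown lists recovered at most 26.1% and 49.2%, which argues against depth as the whole cause there. For CP190 after NURF301 knockdown the difference was -34.4 (exact permutation p = 0.0238). Mock2 replicate 1, at 59.3%, lay below knockdown replicate 1, at 62.2%, so depth stays open there. For Su(Hw) after NURF301 knockdown the difference was -19.0 (exact permutation p = 0.0714), and for NURF301 after CP190 knockdown -23.3 (exact permutation p = 0.143, which with 28 splits could not fall under 0.0714), so depth and knockdown cannot be told apart. For lists with fractional pileups alone, Su(Hw) recovery was 56.3% to 76.2% in 3 NURF301 knockdown lists. In 3 mock lists it was 99.4% to 99.6%, a difference of -31.7 (exact permutation p = 0.1, the lowest possible). These mock lists were all of the mock2 series, with median backgrounds of 29.8 to 40.8, against 3.54 to 6.95 in the knockdown lists. Scaling can therefore not be told apart from series and depth there. Scaling also stays open for CP190, with 1 such mock list (-46.8 after NURF301 and -54.0 after Su(Hw) knockdown), and for NURF301 after Su(Hw) knockdown, with none, besides an effect of the knockdown itself.

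The counts of sites with a peak in every mock and no knockdown library were compared with the other splits of the same libraries. For CP190 and Su(Hw) after NURF301 knockdown, 1 of 84 splits, the real one, gave as many sites. The same held for NURF301 and CP190 after Su(Hw) knockdown. The real values were 1059, 411, 1456 and 2163 and the highest others 216, 59, 22 and 149. The knockdown lists were also the shortest, which by itself favours the real split. These ranks therefore do not exclude chance and are no evidence apart from the peak numbers. For NURF301 and Su(Hw) after their own knockdown, with real values of 3898 and 3726 and highest others of 2 and 0, the splits decide nothing, since every other split is limited by knockdown lists of at most 253 and 96 peaks. The highest other splits for CP190 moved mock2 replicate 1, the CP190 mock library with the fewest peaks, to the knockdown side.

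CP190 and NURF301 peaks missing at Su(Hw) sites after Su(Hw) knockdown may follow from Su(Hw) holding both proteins there, which is a hypothesis. For CP190 the log2 odds ratio exceeded the mock value by 6.89 within strength strata and by 6.23 against thinned lists (unadjusted exact permutation p = 0.0238 for both). Adjusted over 5 comparisons neither passed (adjusted exact permutation p = 0.119 and 0.0595). Each knockdown library still lay above every mock library, at 6.45 to 6.93 against at most 1.43, or 2.42 when thinned. This separation argues against weak sites dropping out and against depth. At CP190 sites with NURF301 it was 5.14 ± 0.30 (n = 3) after Su(Hw) knockdown and -0.28 ± 0.77 (n = 3) after NURF301 knockdown, a difference of 5.42 that argues against a loss of Su(Hw) sites under any knockdown there. At sites without NURF301 the difference of 9.05 leaves this open, since after NURF301 knockdown at least 92.5% of those without Su(Hw) and at least 71.0% of those with it had no peak. For NURF301 the excess of 2.91 over mock libraries leaves weak sites open (exact permutation p = 0.0714). Against thinned lists the excess was 3.43 (unadjusted exact permutation p = 0.0238, adjusted p = 0.0595, which did not pass). Knockdown libraries stood at 2.14 to 2.59 and thinned mock libraries at no more than 0.16, which argues against depth. The value after Su(Hw) knockdown exceeded that after CP190 knockdown by 2.03. Peaks were also missing at 70.8% of sites without Su(Hw), which the hypothesis leaves unexplained.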

How the results depend on the processing

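Thinned lists, the threshold of 20 on the -log10 q, the corrected histone list and the omission of both NURF301 mock libraries with few peaks were chosen only after the data were seen. Of 597 alternative values for 42 results, 227 had their side of the threshold out of reach, by too few libraries for the two-sided test or by a threshold of 5 on the -log10 q, and say nothing about its stability; 6 of them, all for NURF301 after CP190 knockdown, reversed. Of the other 370, 334 kept their direction and their side (or, for values without a test, stayed within the spread between libraries or within 1.5 times the count), 1 kept the direction without passing, 5 passed anew and 30 moved. Some of the 370 were hardly free to change, such as gained NURF301 sites after its own knockdown, where 1 list held 1 peak. The 30 include the lost CP190 sites after CP190 knockdown, which were 0 with any mock library left out. All of the values for the overlap of NURF301 with CP190, Su(Hw) and Mod(mdg4)67.2 and for Mod(mdg4)67.2 with GFP kept their side; the former stood between 73.0% and 84.8%, 15.2% and 16.6%, and 12.7% and 14.9% with each library left out, and at 74.4%, 8.26% and 7.03% for sites in every mock library. A threshold of 5 on the -log10 q changed 1 of 41 values, since the Kc167 lists hold no weaker peaks. Lost sites against a mock series alone gave no value, as 3 against 3 libraries cannot pass, and motifs were not run.

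With a mock series alone, the exact permutation p was 0.1 for the values after NURF301 and Su(Hw) knockdown given here, the smallest possible for 3 against 3 libraries. After CP190 knockdown, with 2 libraries, it was 0.2 for peak numbers against the matching series. The log2 ratios of peak numbers against the matching and the other series were -8.61 and -8.52 (NURF301), -1.19 and -0.72 (CP190) and -0.48 and -0.74 (Su(Hw)) after NURF301 knockdown, and -6.00 and -5.74 (Su(Hw)), -1.79 and -1.88 (NURF301) and -0.94 and -1.40 (CP190) after Su(Hw) knockdown. Recovery differed, in the same order, by -87.6 and -84.2, -54.8 and -35.2, -26.0 and -39.0, -97.0 and -94.3, -61.5 and -64.9, and -43.0 and -60.8 percentage points. The CP190 log2 odds ratio at Su(Hw) sites differed by 8.66 against the mock2 series.

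Replicate numbers do not pair the samples: same-numbered libraries correlated at -0.10 to 0.11 across sites, and only for Su(Hw) after NURF301 knockdown did each library correlate best with the one of its own number, a hint from the data and not from the design. Pairing by number as a block cannot give p under 0.25 with 3 pairs. It gave -8.61, -1.19, -0.48, -6.00, -1.79 and -0.94 for peak numbers, -87.6, -54.8, -26.0, -97.0, -61.5 and -43.0 for recovery and 8.66 for CP190 at Su(Hw) sites (p = 0.25 by the exact permutation of signs). The block was also run for the CP190 knockdown and for the other log2 odds ratios, whose values under it are not given here.

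With each library left out in turn, the ranges of log2 ratios after NURF301 knockdown were -10.46 to -6.47 (NURF301), -1.08 to -0.88 (CP190) and -0.70 to -0.48 (Su(Hw)), and after Su(Hw) knockdown -5.98 to -5.80 (Su(Hw)), -1.96 to -1.79 (NURF301) and -1.28 to -1.12 (CP190). Recovery ranged, in the same order, over -90.7 to -84.0, -47.3 to -31.3, -33.8 to -18.6, -94.1 to -90.3, -68.2 to -60.1 and -53.5 to -39.9 percentage points. These passed with any mock library left out, and no longer with a knockdown library left out, where 2 libraries cannot pass the two-sided test. Lost sites ranged over 0 to 2299 (CP190 after NURF301 knockdown), 0 to 763 (Su(Hw)), 1455 to 2366 (NURF301 after Su(Hw) knockdown) and 2163 to 3394 (CP190), and were 0 for CP190 after CP190 knockdown with any mock library left out, where the smallest attainable p is larger. Gained sites ranged over 0 to 1 (Su(Hw) after NURF301 knockdown) and 3 to 5 (CP190 after Su(Hw) knockdown). The difference in log2 odds ratio ranged over -0.67 to 1.3 (NURF301 after CP190 knockdown), where it was 0.39, 0.82, 0.75 and 1.3 without mock replicate 1 or 2 or mock2 replicate 1 or 3, over -1.53 to -0.39 (CP190) and -1.34 to -0.15 (Su(Hw)) after NURF301 knockdown, and over 2.79 to 4.03 (NURF301) and 5.98 to 7.02 (CP190) after Su(Hw) knockdown.

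Without both NURF301 mock libraries with few peaks, log2 ratios were -8.80 and -2.07 and recovery differences -95.0 and -72.5 after NURF301 and Su(Hw) knockdown (exact permutation p = 0.0571, the smallest for 4 against 3 libraries). Lost NURF301 sites were then 7094 and 4578, against 3898 and 1456. In thinned lists lost sites were 0 (NURF301), 923 (CP190) and 246 (Su(Hw)) after NURF301 knockdown. CP190 sites gained after Su(Hw) knockdown were 5, and recovery of Su(Hw) differed by -19.0 (exact permutation p = 0.0714). Recovery of NURF301 after its own knockdown differed by -24.2 there, which says little, as the ratio of backgrounds rests on few shared sites and few mock peaks are left. At sites in every mock library recovery of NURF301 after CP190 knockdown differed by -10.1, against -28.7. With the threshold of 20, 1304 CP190 sites were lost after NURF301 knockdown. Log2 ratios were then -1.51 (CP190) and -1.07 (Su(Hw)) after NURF301, -1.07 (NURF301) after CP190 and -3.31 (NURF301) after Su(Hw) knockdown, and recovery of Su(Hw) differed by -38.6. In each of these comparisons every knockdown list had a lower median -log10 q than every mock list. The threshold of 20 therefore took a larger share of the knockdown peaks, so these larger differences are no separate evidence of loss. Summits extended by 150 bp gave 6 gained sites (Su(Hw) after NURF301 knockdown), 17 (CP190 after CP190 knockdown), 10 (NURF301) and 14 (CP190 after Su(Hw) knockdown). The difference in log2 odds ratio was then -2.67 for CP190 after NURF301 and 3.86 for NURF301 after Su(Hw) knockdown (exact permutation p = 0.0238). For the latter it was 2.96 with 5 strata and 3.43 in thinned lists. For NURF301 after CP190 knockdown it was 0.18 without strata, 0.35 in thinned lists and -1.08 against the matching mock series. For CP190 after NURF301 knockdown these values were -0.01, -1.97 and -2.27. A boundary window of 1000 bp gave 18 passing tests of a gene list with an antibody, against 10 of 68, and the histone list without HisCl1, HisRS and HisT gave 12. Except where stated, the cause was not tested. Depth limits what absence means: a missing peak is one not called in that list.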

Other observations

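NURF301 was dense on chromosome 4, a small chromosome rich in heterochromatin. It had 69.7 reference sites per Mb there, against 51.7 to 61.0 on the other chromosomes, while CP190 had 23.5 per Mb there against 58.8 to 66.8 elsewhere and Su(Hw) 10.6 against 30.1 to 39.0. Of the named NURF301 sites that disappeared after NURF301 knockdown, anne, Crk, 4E-T, Dyrk3 with Cadps, myo and CaMKII lie on chromosome 4. None of these carried CP190. The difference between chromosomes was not tested.

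Sites that carried NURF301, CP190, Su(Hw) and Mod(mdg4)67.2 in mock cells kept more CP190 peaks after CP190 knockdown, and more Su(Hw) peaks after Su(Hw) knockdown, than the other classes of these proteins. After CP190 knockdown CP190 was recovered at 48.6% ± 2.99 (n = 2) of them, against 3.32% ± 0.361 of sites with Su(Hw) and Mod(mdg4)67.2 but no NURF301. After Su(Hw) knockdown Su(Hw) was recovered at 7.77% ± 1.08 (n = 3) of them, against 0.617% ± 0.178 of sites with CP190 and Mod(mdg4)67.2 but no NURF301. The differences between these classes were not tested. Peaks in the lists of a protein after its own knockdown were narrow: the narrowest had 147 bp, and the median width was 278 and 286 bp for CP190 after CP190 knockdown, against 520 to 606 bp in mock lists.

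A hypothesis of this part is that NURF301 joins Su(Hw) sites through Mod(mdg4)67.2 or something that goes with it. The test within strength deciles was chosen only after the result was seen, while those away from gene boundaries and with the GFP-tagged protein were stated before it. Within deciles of Su(Hw) strength the log2 odds ratio was 5.07, which argues against strong sites carrying both proteins as the cause. Away from gene boundaries it was 5.25 (95% interval 4.78 to 5.72), which argues against boundaries as a shared cause. With GFP-tagged Mod(mdg4) in place of the antibody it was 4.63 (4.30 to 4.96), which argues against an antibody that also recognises NURF301 sites. These data may thus be consistent with a link between both proteins, but no knockdown of Mod(mdg4) was part of the design, so the direction stays untested.

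The peak names inside the NURF301 lists of Su(Hw) knockdown replicates 2 and 3 carry the numbers 3 and 4. The group of these lists is the same under either numbering.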
